A study of Mus musculus with 9 samples.

How the data were processed

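The series holds 9 mRNA-seq libraries of mouse monocyte-derived dendritic cells from the C57BL/6 strain. Per the labels' protocols, monocytes were isolated from bone marrow, cultured for 7 days with 100 ng/mL GM-CSF and 50 ng/mL IL-4, and sorted by flow cytometry. For the treated groups the protocols give 24 h of priming with interferon α, followed by 18 h with R837 alone or R837 together with spermidine. Libraries were made with an mRNA-seq kit after Trizol extraction, per the labels' protocols. There were 3 groups of 3 libraries, taken from the sample titles and treatment labels: control (no stimulation), R837, and R837 with spermidine. The labels do not say whether the control cells were primed with interferon α, nor whether replicates came from separate cultures or animals. The p-values therefore measure the spread between these libraries, which may be technical.

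The deposited values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), one value per gene and library, per the file headers. HISAT2 and StringTie are named in the submitters' processing notes without versions, as are the mouse builds mm8 and mm10 without a role. The annotation release and any filter were not given in the sources used here. Each deposited table listed the same 52550 versioned Ensembl gene identifiers. Symbols, positions and transcript sequences were taken from GENCODE mouse release 21 (GRCm 38, mm10). Without the version suffix 52403 identifiers (99.7%) matched that release, and 93.3% matched with it. All positions given are those of GENCODE on mm10. Values of the 73 symbols with several identifiers were summed. All 37 genes of the mitochondrial chromosome were listed at 0 in every library, so a value of 0 in these tables need not mean that a transcript was absent.

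FPKM values carry no counts. The depth was read from the low values of genes with a single transcript, whose FPKM multiplied by length is a whole multiple of what 1 fragment was worth. This step corresponded to between 10600000 and 14400000 units per library. Whether the unit was a read or a read pair was not settled. At this depth an FPKM of 1 for a transcript of 1 kb rests on 11 to 14 units, so values near and below 1 carry a large counting error. The relative depth spanned 1.36-fold, and the FPKM values of a library summed to between 310220 and 326222.

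Genes with an FPKM of 1 or more in at least 3 of the 9 libraries were tested, which left 11768. Values were transformed to log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. All 9 libraries entered one limma fit (limma 3.58.1 in R 4.3.3; lmFit, and eBayes with a mean-variance trend), with 3 contrasts: R837 against control, R837 with spermidine against R837, and R837 with spermidine against control. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. A gene is said to have risen or fallen only where it passed. The test was two-sided. The files hold no counts, so the planned count-based tests were not run. The fit was tested on simulated data with known changes for the 11768 genes. Changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, so recovery of lower genes was not tried. The simulated noise was independent between genes, so errors shared by genes were not tried either. For R837 against control 64% of the genes changed by 1.5-fold and 88% of those changed by 2-fold were recovered, with 4.55% false calls. For R837 with spermidine against R837 the shares were 52% and 89%, with 6.25% false calls, and for R837 with spermidine against control 58% and 82%, with 2.45% false calls.

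A set of 40 gene lists (pathways, stress programmes, RNA quality, and markers of cell types) was fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The 30 lists with at least 5 tested members were tested with camera from limma with its preset correlation of 0.01, and the adjusted p over lists was also obtained with a correlation estimated for each list and with fry. A count of list members past the threshold refers to the adjustment over all tested genes unless it is given as adjusted over the list alone. Named genes were, for the first and second contrasts, the 8 largest rises and the 8 largest falls among genes past the threshold with a mean FPKM of at least 5 in the higher group and no overlap of libraries, leaving out predicted genes. To these were added up to 4 members of each list with the largest changes, and a fixed set of genes of the interferon, cytokine, co-stimulation and polyamine systems. The rule gave 233 genes. The text gives values for 108 of them, a selection made after their values were seen, and the closing section counts changes over all 233. Markers of blood and marrow cells and the histone gene Hist1h2ak, below the filter, were chosen after their values were seen.

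The alternatives were TPM, a pseudocount of 0.1, no filter, a filter on a mean FPKM of at least 5, median-of-ratios size factors, quantile normalization, the replicate number as a block, a fit of the compared groups alone, a required fold of 2, weights per library, the highest row per symbol, and the omission of each library in turn. A correction for transcript GC content was added after seeing the data. It removed from each library the lowess trend of its deviation from the gene means on GC content, which was available for 99.9% of the tested genes. Correlations between the effects of R837 and of added spermidine were set beside 100 simulations with the fitted spread. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.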

Results

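The measurement was the polyadenylated transcriptome of mouse monocyte-derived dendritic cells, antigen-presenting cells grown from bone marrow monocytes. Of 9 libraries, 3 came from control cells without stimulation, 3 from cells given R837 (imiquimod, a small-molecule agonist of Toll-like receptor 7), and 3 from cells given R837 together with spermidine, a natural polyamine. Values are FPKM. The depth read from the values was 11400000, 11600000 and 11500000 units in the controls, 11000000, 10900000 and 12600000 in the R837 libraries, and 10600000, 14400000 and 12900000 in the R837 with spermidine libraries. The test covered 11768 genes. Pearson's correlation between libraries of a group lay between 0.984 and 0.985 for the controls, 0.967 and 0.981 for R837, and 0.983 and 0.986 for R837 with spermidine.

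R837 against control answers what the agonist did to the cells. The labels give interferon α priming for the treated cells and do not say whether the control was primed, so this comparison may include the priming. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007), which encodes tumour necrosis factor, rose from 24.1 ± 1.83 FPKM in the controls to 1239 ± 88.8 with R837 (SD, n = 3), 51.4 times as high, with a log2 change of 5.63 ± 0.09 (SE) and a limma adjusted p of 3.9e-09. Il12b (ENSMUSG00000004296.14, chromosome 11, 44400063 to 44414033), the shared subunit of interleukins 12 and 23, rose from 4.27 ± 0.738 to 330 ± 30.6 FPKM. Cxcl1, a neutrophil-attracting chemokine, had the largest log2 change of the rule's named rises, 6.40, and Cxcl2 rose from 19.8 ± 3.58 to 860 ± 165 FPKM. The prostaglandin synthase gene Ptgs2 rose from 2.88 ± 0.494 to 127 ± 29.6 FPKM, and Il1b from 3.53 ± 0.568 to 147 ± 58.7.

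Of the 30 measured members of the cytokine and chemokine list, 28 rose and 0 fell, with 2 not called, and the limma camera test placed the list up with an adjusted p of 3.1e-30 (0.016 with an estimated correlation). The count was also 28 when adjusted over the list alone. The cytokine genes Il6, Il10, Il12a and Il23a, near 0 in the controls at 0.191, 0.222, 0.0132 and 0.052 FPKM, reached means of 18.7, 12.9, 9.38 and 1.82. All 22 NF-κB target and feedback genes rose, also when adjusted over the list alone (limma camera adjusted p = 2e-26; 0.016 with an estimated correlation). Among them Nfkbia, which encodes the inhibitor that holds NF-κB in the cytoplasm, rose from 51.8 ± 3.57 to 512 ± 63.3 FPKM, Nfkbiz by 5.09 on the log2 scale, and the adhesion gene Icam1 by 3.51.

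Dendritic cell maturation genes rose in 16 of 20 cases, 17 when adjusted over the list alone, with 0 lower and 4 not called (limma camera adjusted p = 1.7e-12; 0.0059 with an estimated correlation). The co-stimulatory receptor gene Cd40 rose from 4.48 ± 0.318 to 113 ± 17.4 FPKM, Icosl from 2.02 ± 0.11 to 27.9 ± 0.611, and Cd83 from 14.7 ± 1.25 to 52.2 ± 8.46. The ligand genes Cd80 and Cd86 did not pass, with limma adjusted p-values of 0.073 and 0.11. Without R837 replicate 2 Cd80 passed as a rise of 1.21 (limma adjusted p = 7.9e-05), and without R837 replicate 3 Cd86 passed as a fall, with a log2 change of -0.54 (limma adjusted p = 0.023). Cd80 also passed under both other scalings, with 0.93 and 0.87.

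Genes that restrain signalling were induced as well. Of 20 such brakes 13 rose and 5 fell, 18 when adjusted over the list alone (limma camera adjusted p = 4.3e-07; 0.086 with an estimated correlation). Socs3, a suppressor of cytokine signalling, rose from 5.52 ± 0.521 to 162 ± 23.1 FPKM, Socs1 by 2.13 on the log2 scale and Irak3 by 1.86. The phosphatase gene Dusp1 fell from 70.9 ± 1.19 to 61.2 ± 3.53 FPKM (limma adjusted p = 0.034). That fall did not pass without any 1 of the controls (0.072, 0.10 and 0.089), R837 replicates 1 and 3 (0.093 and 0.096) or R837 with spermidine replicate 3 (0.053), nor with median-of-ratios scaling (0.78).

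In the Toll-like receptor 7 pathway 8 of 23 members rose and 4 fell, 12 when adjusted over the list alone (limma camera adjusted p = 0.020; 0.086 with an estimated correlation). The kinase gene Ikbke rose by 1.89 on the log2 scale, and the adaptor gene Myd88 from 26.5 ± 2.83 to 40.6 ± 4.06 FPKM. Tlr7 itself stood at 5.18 ± 0.35 and 4.35 ± 0.909 FPKM and did not pass (limma adjusted p = 0.22). The fallen members numbered 2 without control replicate 2 or 3. Of 12 MHC class II genes 3 rose and 1 fell (limma camera adjusted p = 0.026; 0.57 with an estimated correlation), 4 when adjusted over the list alone. This call was lost without R837 replicate 2 (0.16), without control replicate 3 (0.051) and with the filter on a mean FPKM of at least 5 (0.25). Ciita, the class II transactivator, rose from 6.04 ± 0.509 to 39 ± 4.64 FPKM, whereas H2-Ab1 stood at 511 ± 11.8 and 517 ± 55.2 FPKM and did not pass. The fallen gene was Ctss, which encodes the protease cathepsin S, at 3416 ± 221 and 2661 ± 186 FPKM. It did not pass under other scalings, with a log2 change of -0.18 for median-of-ratios and of the opposite sign, 0.16, for quantile normalization. Of 16 MHC class I genes 5 rose and 0 fell, also 5 when adjusted over the list alone, with the proteasome activator gene Psme2 at 41.4 ± 3.1 and 81.7 ± 2.25 FPKM (limma camera adjusted p = 0.0025; 0.26 with an estimated correlation).

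Interferon-stimulated genes, which may have responded to the priming, rose in 18 of 35 cases with 1 lower and 16 not called, 19 when adjusted over the list alone (limma camera adjusted p = 1.6e-08; 0.016 with an estimated correlation). Isg15 rose from 89.1 ± 1.87 to 249 ± 21.5 FPKM and Ifit1 from 7.71 ± 0.348 to 25.6 ± 8.13. The ADP-ribosyltransferase gene Parp14 rose from 9.42 ± 0.354 to 50.3 ± 3.03 FPKM, and Ifi205 from 3.98 ± 0.235 to 36.7 ± 19.5. Irf7, which encodes a transcription factor of the interferon response, fell from 101 ± 3.93 to 81.3 ± 7.01 FPKM, a call lost with median-of-ratios scaling (limma adjusted p = 0.21). None of the 8 type I interferon and related genes on the interferon list reached the filter, so 0 were tested.

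Lysosomal genes fell in 22 of 27 cases, 23 when adjusted over the list alone (limma camera adjusted p = 0.00018; 0.021 with an estimated correlation). With median-of-ratios scaling 12 fell and 1 rose. Lipa, the lysosomal acid lipase, fell from 431 ± 9.89 to 232 ± 33.3 FPKM and the β-glucuronidase gene Gusb from 111 ± 2.65 to 69.9 ± 5.43. Of 17 genes of lipid handling controlled by LXR, 11 fell and 1 rose, 13 when adjusted over the list alone (limma camera adjusted p = 0.020; 0.086 with an estimated correlation; 0.056 with the filter on a mean FPKM of at least 5). Abcg1, a cholesterol exporter, fell from 142 ± 2.59 to 55.4 ± 5.9 FPKM, Pparg from 22.5 ± 1.02 to 8.06 ± 1.16 and the lipid droplet gene Plin2 from 496 ± 23.1 to 203 ± 6.35. Cell cycle genes fell in 22 of 30 cases and 1 rose, 24 when adjusted over the list alone (limma camera adjusted p = 0.0015; 0.086 with an estimated correlation; 14 fell with median-of-ratios scaling). With the same filter, which left 9 members, the cell cycle call was lost (0.19). The mitotic genes Cenpa and Plk1 fell by 1.03 and by 0.90 on the log2 scale, whereas the proliferation marker Mki67 rose from 10.5 ± 0.494 to 24.9 ± 9.7 FPKM.

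Among the rule's largest falls, Lrrc14b dropped from 51.7 ± 0.968 to 8.17 ± 0.351 FPKM, Lyl1 from 23.5 ± 0.784 to 4.09 ± 0.781, Tmem154 from 64.6 ± 2.27 to 13.5 ± 0.272, and the cannabinoid receptor gene Cnr2 from 9.97 ± 0.391 to 1.47 ± 0.723. Dedd2, Mrgpre and Gcnt1 fell as well, with log2 changes of -2.31, -2.24 and -2.15. Slc40a1 (ENSMUSG00000025993.10, chromosome 1, 45908068 to 45926523), the iron exporter ferroportin, fell from 18.1 ± 1.46 to 4.45 ± 0.494 FPKM, and the phagocytic receptor gene Mertk from 20.2 ± 1.79 to 8.55 ± 0.665.

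Further lists were called without an estimated correlation. The integrated stress response list was up with 7 of 25 members higher and 3 lower (limma camera adjusted p = 0.026; 0.54 with an estimated correlation), with Nupr1 at 7.18 ± 0.305 and 17.2 ± 1.47 FPKM. Its call was lost without R837 replicate 2 (0.14), without control replicate 3 (0.051, with 4 members higher), with quantile normalization (0.21) and with the filter on a mean FPKM of at least 5 (0.087). The interleukin 4 response list, with 5 of 16 higher and 3 lower, had a limma camera adjusted p of 0.027 (0.11 with an estimated correlation; 0.059 and 0.081 under both other scalings; 0.087 with that filter). Its member Irf4 rose from 15.2 ± 0.0829 to 41 ± 3.42 FPKM. Immediate early genes were listed for RNA quality because handling stress can change them, and an effect of R837 cannot be told apart from it here. They showed 8 of 16 higher and 5 lower (limma camera adjusted p = 0.027, 0.36 with an estimated correlation, and 0.057 and 0.10 under both other scalings). Junb rose by 1.20 on the log2 scale while Fos fell by 1.30 and Jun fell by 1.13. Without control replicate 2 the counts were 5 and 3, and 3 fell without control replicate 1 or 3 or R837 replicate 3.

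The limma camera test called no other list in this comparison. Polyamine metabolism showed 2 of 20 members higher and 8 lower (adjusted p = 0.59), with 5 lower without control replicate 2. Odc1, the ornithine decarboxylase gene, rose from 39.9 ± 2.75 to 58.7 ± 6.19 FPKM, Arg2 from 13.8 ± 1.67 to 46 ± 9.35, and the methionine salvage gene Adi1 fell from 30.7 ± 2.65 to 7.65 ± 0.72. Smox, the spermine oxidase gene, stood at 17.2 ± 1.24 and 16.5 ± 1.74 FPKM and did not pass. Autophagy showed 3 of 25 members higher and 10 lower (limma camera adjusted p = 0.59), with 6, 5 and 5 lower without control replicates 1, 2 and 3. Its receptor gene Sqstm1 rose from 744 ± 104 to 1357 ± 11.7 FPKM. Adjusted limma camera p-values were 0.12 for nuclear oxidative phosphorylation genes, 0.36 for cholesterol synthesis, 0.85 for glycolysis, 0.97 for NRF2 targets, 0.41 for heat shock, 0.72 for the unfolded protein response and for p53 targets, and 0.29 for the inflammasome. Among their members Sdha fell by 0.58, Bbc3 fell by 1.30 and Nlrp3 rose by 2.56 on the log2 scale. Oxidative phosphorylation passed, as lower, without R837 replicate 2 (0.029), with quantile normalization (0.0046) and with no filter (0.0051). The NRF2 and glycolysis lists had median log2 changes of -0.15 and -0.19, while camera, which compares a list with the other genes, had them up without a call.

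In all 1604 genes rose and 3477 fell (limma, adjusted p), of which 588 and 372 changed by 2-fold or more. Without overlap between the libraries of both groups were 54.0% of the genes, where chance gives 10%. The median log2 change of all tested genes was -0.17. Median-of-ratios scaling shifted that median by 0.15 and gave 2135 higher and 1941 lower, so the share of higher calls went from 31.6% to 52.4%, and quantile normalization gave 43.6%. FPKM values cannot tell which scale is right, so small falls rest on the scaling.

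**Figure D1:**
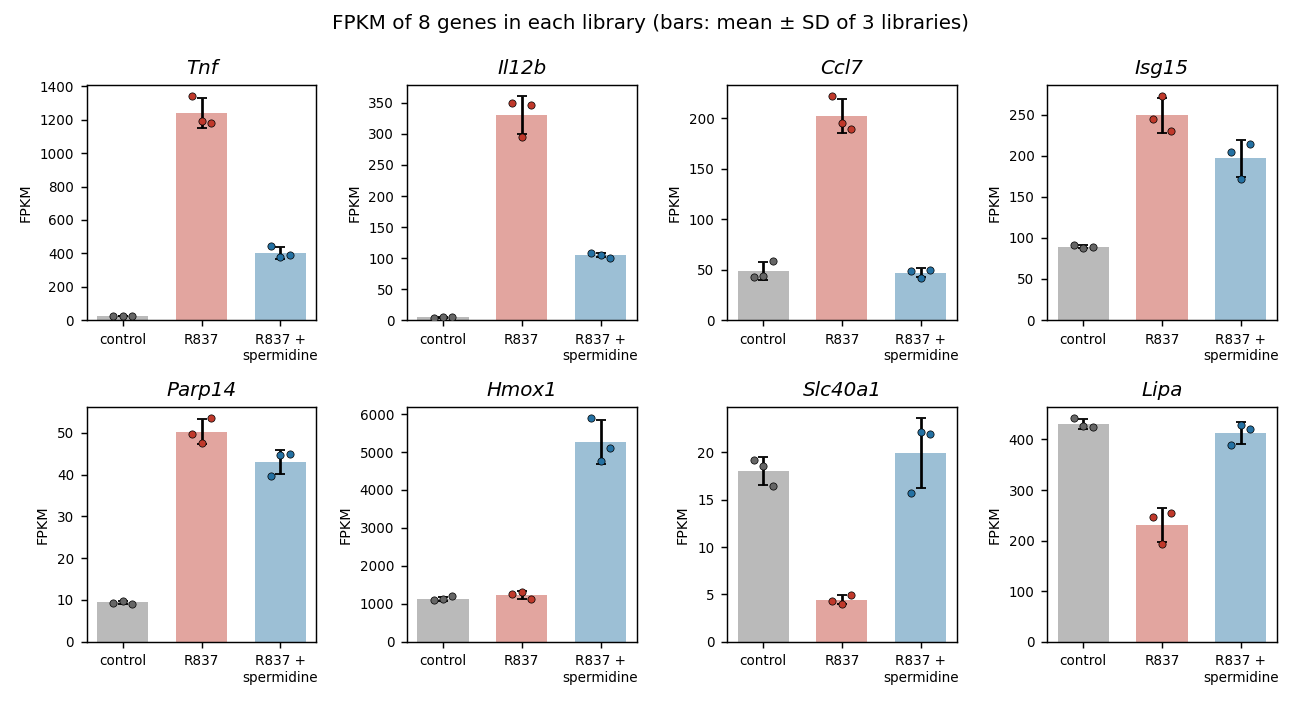
FPKM of 8 genes in each library of the control, R837, and R837 with spermidine groups, with bars for the mean, error bars for the SD of 3 libraries and dots for the libraries. Tnf stood at 24.1, 1239 and 402 FPKM, Ccl7 at 48.4, 202 and 46.8, and Hmox1 at 1136, 1234 and 5259.

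R837 with spermidine against R837 answers what spermidine changed in cells given the agonist. Hmox1 (ENSMUSG00000005413.8, chromosome 8, 75093621 to 75100589), which encodes the heme-degrading enzyme heme oxygenase 1, rose from 1234 ± 100 to 5259 ± 580 FPKM, 4.26 times as high (log2 change 2.09 ± 0.10, SE; limma adjusted p = 2.2e-05), against 1136 ± 56 in the controls. Slc40a1, the ferroportin gene that R837 had lowered, rose from 4.45 ± 0.494 to 19.9 ± 3.71 FPKM. Of 22 targets of the oxidative stress regulator NRF2, 17 rose and 0 fell, 19 when adjusted over the list alone (limma camera adjusted p = 2.4e-17; 0.0021 with an estimated correlation). The glutathione synthesis gene Gclm rose from 5.45 ± 0.512 to 23.4 ± 6.67 FPKM, the carbonyl reductase gene Cbr3 from 8.76 ± 0.86 to 29.1 ± 0.801 and the catalase gene Cat from 63.3 ± 3.56 to 117 ± 2.08.

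The other large rises included Idh1, the cytosolic isocitrate dehydrogenase, from 10.9 ± 2.43 to 34.1 ± 3.48 FPKM, and Mir7062, a short microRNA gene, from 2.87 ± 2 to 10.8 ± 2.29. At these depths the values of so short a gene rest on few units. The peroxiredoxin gene Prdx1 rose from 292 ± 176 to 945 ± 95.3 FPKM (limma adjusted p = 0.025), which did not pass without R837 with spermidine replicate 1, 2 or 3 (0.053, 0.081 and 0.079). The caspase gene Casp1 rose from 17.4 ± 12.3 to 53.8 ± 19 FPKM (limma adjusted p = 0.040). It did not pass without control replicate 1, 2 or 3 (0.057, 0.064 and 0.060), R837 replicate 1 or 2 (0.084 and 0.068), or R837 with spermidine replicate 2 or 3 (0.11 and 0.13). Txnrd1, the thioredoxin reductase gene, had risen with R837 from 61.1 ± 0.848 to 127 ± 7.12 FPKM and stood at 195 ± 14.4 with spermidine added.

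Cytokine genes fell with spermidine. Tnf went from 1239 ± 88.8 to 402 ± 35 FPKM (log2 change -1.62 ± 0.09, SE; limma adjusted p = 3.7e-05) and Il12b from 330 ± 30.6 to 105 ± 3.67. The monocyte-attracting chemokine gene Ccl7 (ENSMUSG00000035373.2, chromosome 11, 82045712 to 82047525) went from 202 ± 17.3 to 46.8 ± 4.48 FPKM, beside 48.4 ± 9.06 in the controls. Il12a, the other subunit of interleukin 12, fell from 9.38 ± 0.962 to 1 ± 0.465 FPKM, Il27 from 34.2 ± 6.69 to 7.63 ± 1.09, and Csf2, which encodes GM-CSF, from 5.59 ± 1.39 to 0.491 ± 0.263. Of the 30 measured members of the list 23 fell and 0 rose, 25 when adjusted over the list alone (limma camera adjusted p = 4.2e-18; 0.049 with an estimated correlation). Il1b, Il10, Il23a and Cxcl1 were among them, with log2 changes of -1.53, -1.01, -1.01 and -1.05.

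Some cytokine calls changed when 1 library was left out. Il6 went from 18.7 ± 10.6 to 8.2 ± 1.4 FPKM and did not pass (limma adjusted p = 0.17), but passed without R837 replicate 2 (0.0018). Cxcl2, at 569 ± 143 FPKM with spermidine, did not pass (limma adjusted p = 0.078) except without R837 with spermidine replicate 1 (0.035), and Cxcl3 did not pass (0.34). Cxcl10 fell from 30.4 ± 3.01 to 21.6 ± 1.96 FPKM (limma adjusted p = 0.015), a call lost without R837 with spermidine replicate 2 or 3 (0.062 and 0.055). The microRNA host gene Mir155hg fell from 8.78 ± 4.72 to 0.903 ± 1.33 FPKM (limma adjusted p = 0.026), a call lost without R837 replicate 2 or 3 (0.066 and 0.062) and without R837 with spermidine replicate 1 or 3 (0.075 and 0.094). The other large falls were Tnfsf9, Edn1 and Tagap, with log2 changes of -1.89, -1.77 and -1.77.

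NF-κB target genes fell in 17 of 22 cases, also 17 when adjusted over the list alone, and 0 rose (limma camera adjusted p = 4.8e-11; 0.085 with an estimated correlation). The count was 11 without R837 with spermidine replicate 2 or 3. Nfkbia went from 512 ± 63.3 to 287 ± 16.9 FPKM and Icam1 from 331 ± 41.2 to 177 ± 3. Maturation genes fell in 9 of 20 cases, also 9 when adjusted over the list alone, with 0 higher and 11 not called (limma camera adjusted p = 0.00062; 0.049 with an estimated correlation). Cd40 went from 113 ± 17.4 to 49.3 ± 4.06 FPKM and Cd83 from 52.2 ± 8.46 to 28.7 ± 1.47, while Cd80 and Cd86 did not pass. Of the 20 brakes 10 fell and 4 rose, 15 when adjusted over the list alone (limma camera adjusted p = 0.030; 0.49 with an estimated correlation). This call was lost without R837 replicate 2 (0.086), with the GC trend removed (0.069) and with the filter on a mean FPKM of at least 5 (0.10), and 6 fell without R837 with spermidine replicate 3. Socs3 went from 162 ± 23.1 to 59.7 ± 1.9 FPKM and Dusp1 rose from 61.2 ± 3.53 to 101 ± 4.37. Of 12 MHC class II genes 3 fell, 5 when adjusted over the list alone, Ciita from 39 ± 4.64 to 18.2 ± 0.519 FPKM (limma camera adjusted p = 0.020; 0.60 with an estimated correlation). The class II call was lost without R837 replicate 2 (0.15) and with the same filter (0.13), and 1 member fell without R837 with spermidine replicate 2 or 3.

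Heat shock genes rose in 7 of 14 cases, 11 when adjusted over the list alone, with 0 lower (limma camera adjusted p = 5.9e-06; 0.029 with an estimated correlation). The chaperone gene Hsph1 rose from 13.6 ± 1.07 to 24.6 ± 0.892 FPKM. Hspa1a and Hspa1b, near-identical copies whose reads cannot be assigned with certainty, rose from 13.2 ± 1.56 to 23.6 ± 0.383 and from 13.1 ± 1.3 to 22.6 ± 0.132. The chaperone gene Hspa8 rose from 70.6 ± 18.5 to 126 ± 19.3 FPKM (limma adjusted p = 0.021), a call lost without R837 replicate 1 (0.050) or R837 with spermidine replicate 2 or 3 (0.064 and 0.082). The list's count was 4 without any 1 of those same libraries.

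Genes of the unfolded protein response rose in 7 of 18 cases with 1 lower, 8 when adjusted over the list alone (limma camera adjusted p = 0.023; 0.12 with an estimated correlation). The call was lost without R837 replicate 3 (0.074). The number of risen members was 1 without R837 with spermidine replicate 2 or 3, 4 without R837 with spermidine replicate 1 or R837 replicate 2, and 3 without any 1 control. Xbp1 rose from 13.9 ± 0.56 to 18.4 ± 1.25 FPKM. Hspa5 rose from 96.7 ± 8.93 to 143 ± 26 FPKM (limma adjusted p = 0.025), not without R837 replicate 2 or 3 (0.054 and 0.050) or R837 with spermidine replicate 2 or 3 (0.061 and 0.068). Herpud1 fell from 63.1 ± 9.43 to 43.6 ± 4.8 FPKM (limma adjusted p = 0.020), not without R837 with spermidine replicate 2 or 3 (0.076 and 0.076).

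The glycolysis list was up with 3 of 21 higher and 2 lower, 5 when adjusted over the list alone (limma camera adjusted p = 0.020; 0.49 with an estimated correlation). Pgk1 rose from 112 ± 3.74 to 168 ± 4.1 FPKM, Egln3 rose by 0.55 on the log2 scale and Hk2 fell from 33.9 ± 2.33 to 25.5 ± 0.497 FPKM. The list's call was lost without R837 replicate 1 (0.098) or 3 (0.074), and 7 members rose without R837 replicate 2. The cell cycle list was down with 5 of 30 lower and 1 higher, 6 when adjusted over the list alone (limma camera adjusted p = 0.00062; 0.085 with an estimated correlation). With the filter on a mean FPKM of at least 5, which left 9 members, the cell cycle call was lost (0.15). The lower members numbered 1 and 0 without R837 with spermidine replicates 2 and 3, 3 without replicate 1 of that group or any 1 control, 2 without R837 replicate 1, and 8 without R837 replicate 2. Rrm2 fell from 9.28 ± 1.59 to 5.47 ± 0.919 FPKM and Ccna2 from 2.92 ± 0.507 to 1.65 ± 0.159, while Pcna rose from 72.2 ± 4.38 to 105 ± 11.4. The fall of Rrm2 was lost without R837 with spermidine replicate 2 or 3 (limma adjusted p = 0.050 and 0.050) and that of Ccna2 without replicate 3 (0.053). The neutrophil list was down with 1 of 9 members lower, Csf3r from 11.9 ± 0.752 to 5.65 ± 0.324 FPKM, 4 when adjusted over the list alone (limma camera adjusted p = 0.020; 0.60 with an estimated correlation). Its lower members numbered 4, 2 and 3 without R837 replicates 1, 2 and 3. Of the 14 neutrophil markers that reached 1 FPKM 13 were highest in R837 replicate 3, which raises the R837 side, and without that library the list was still called (limma camera adjusted p = 0.045) with its median log2 change at -0.25 in place of -0.85.

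The interferon-stimulated list was not called when spermidine was added (limma camera adjusted p = 0.87), with 1 of 35 members lower, 0 higher and 0 when adjusted over the list alone. That member, Isg15, went from 249 ± 21.5 to 197 ± 22.4 FPKM (limma adjusted p = 0.049), and the omission of any 1 library except R837 replicate 3 ended its call (0.067 to 0.14). Ifit1 stood at 25.6 ± 8.13 and 26.6 ± 2.86 FPKM, and Parp14 at 50.3 ± 3.03 and 43 ± 2.98. Polyamine metabolism was not called (limma camera adjusted p = 0.056), with 3 of 20 members higher and 0 lower, also 3 when adjusted over the list alone. It passed without R837 replicate 2 (0.016, with 6 higher), R837 with spermidine replicate 2 (0.036) or control replicate 1 (0.047), with quantile normalization (0.040), and with the GC trend removed (0.026, with 4 higher). Sat1, the spermidine acetyltransferase gene, rose from 38 ± 5.36 to 64.2 ± 3.46 FPKM, Arg1 from 2.15 ± 0.105 to 4.86 ± 0.266 and Adi1 from 7.65 ± 0.72 to 11.4 ± 0.532. Odc1 and Smox did not pass.

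Other lists were not called, with limma camera adjusted p-values of 0.30 for autophagy, 0.33 for the lysosome, 0.36 for oxidative phosphorylation, 0.57 for cholesterol synthesis, 0.93 for LXR targets, 0.10 for the integrated stress response, 0.79 for p53 targets, 0.87 for the interleukin 4 response, 0.57 for the inflammasome, 0.55 for the Toll-like receptor 7 pathway, 0.11 for MHC class I and 0.30 for immediate early genes. MHC class I passed, as lower, without R837 replicate 1 (0.042) and with no filter (0.019), and the integrated stress response, as lower, with no filter (0.011). Single members passed. Lipa rose from 232 ± 33.3 to 413 ± 21.3 FPKM and the p53 target Trp53inp1 from 1.78 ± 0.408 to 4.77 ± 0.855, while Ccl17 fell from 62.4 ± 7.71 to 34.1 ± 4.74 and Nr4a3 from 8.93 ± 0.672 to 4.95 ± 0.435. Myd88 did not pass (limma adjusted p = 0.052) except without R837 replicate 1 (0.040).

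**Figure D2:**
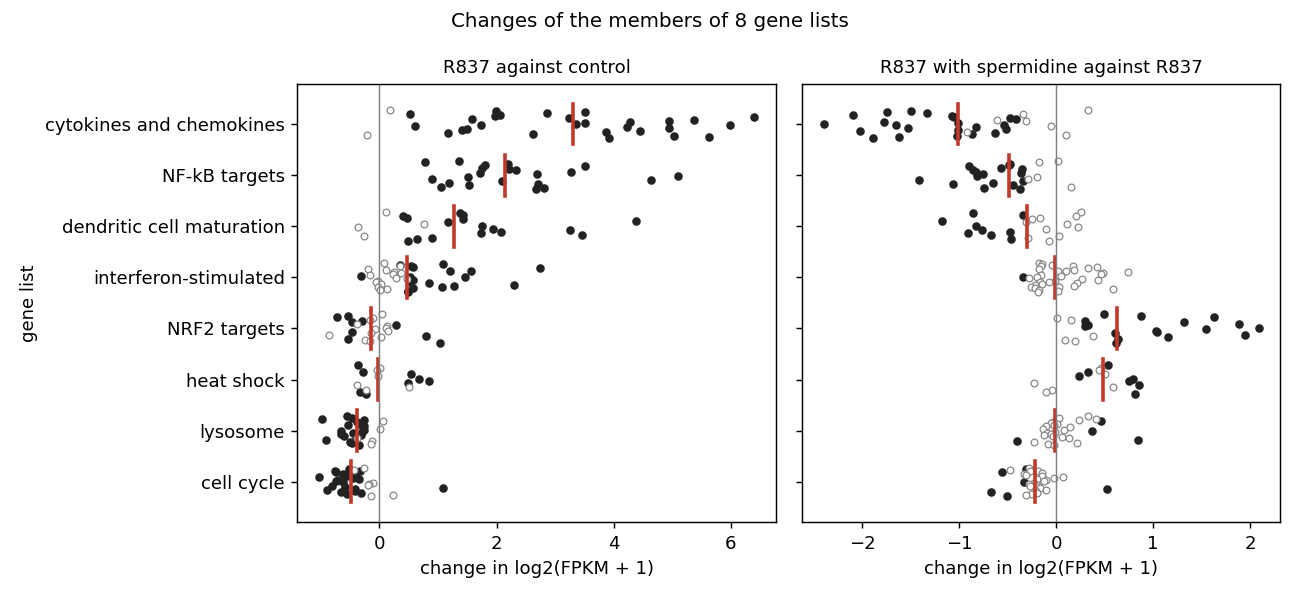
Change in log2(FPKM + 1) of each measured member of 8 gene lists for R837 against control and for R837 with spermidine against R837, with filled dots for genes past the threshold, open dots for others and a red line at the list's median. The medians were 3.30 and -1.01 for cytokines and chemokines, 0.48 and -0.01 for interferon-stimulated genes, and -0.15 and 0.63 for NRF2 targets.

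In all 659 genes rose and 942 fell (limma, adjusted p), of which 63 and 53 changed by 2-fold or more. A fit of both groups alone gave 301 higher and 456 lower. Without overlap were 32.9% of the genes, where chance gives 10%. The counts changed when 1 library was left out. Rises numbered 432 without R837 replicate 1 or R837 with spermidine replicate 1, and 290 without R837 with spermidine replicate 2 or 3. Falls numbered 476 and 459 without R837 with spermidine replicates 2 and 3. Without control replicates 1, 2 and 3 rises numbered 495, 454 and 497, and falls 699, 674 and 715. The controls hold no value of this comparison, so those losses come from the estimate of the spread. The change of a gene was related to its transcripts' GC content across genes (Spearman's rho -0.36). The rho was -0.02 for R837 against control and -0.25 for R837 with spermidine against control, and genes are not independent replicates. Within the R837 group the deviation of replicate 2 rose with GC content (rho 0.63) and that of replicates 1 and 3 fell (-0.43 and -0.48), as the deviations of a group sum to 0. The values of the other groups lay between -0.17 and 0.18. Deviations within a group cannot place the trend between groups, which was found in both comparisons that hold the spermidine libraries.

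**Figure D3:**
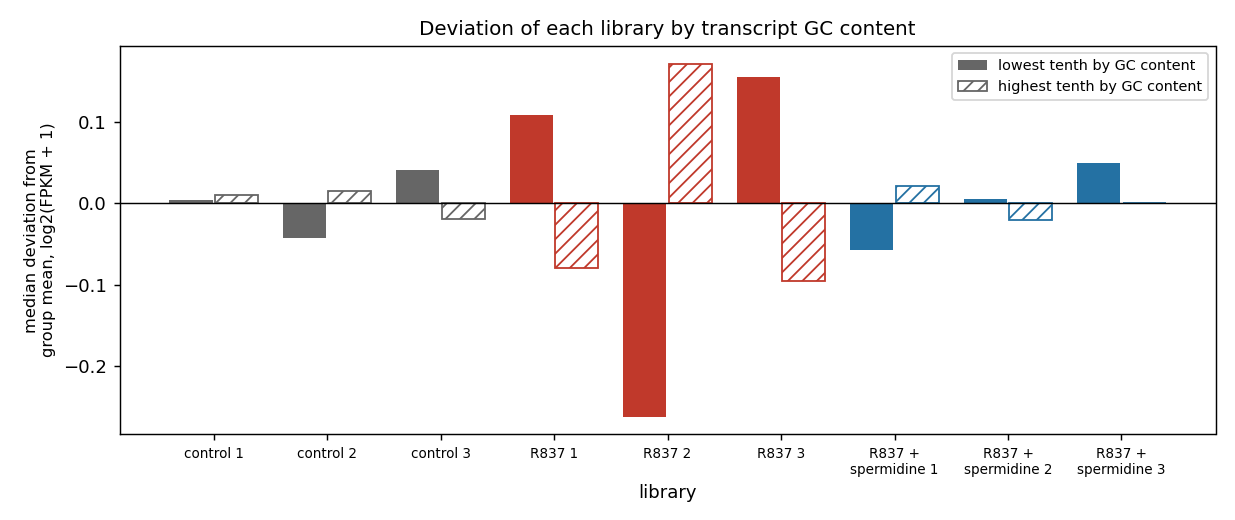
Median deviation from the group mean, in log2(FPKM + 1), of the genes with the lowest 10% (filled bars) and the highest 10% (hatched bars) of transcript GC content, for each of the 9 libraries. R837 replicate 2 stood at -0.26 and 0.17.

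R837 with spermidine against control holds what remained of the response to R837 together with any effect of spermidine itself. No group had spermidine alone, so these parts cannot be separated. Tnf was at 402 ± 35 FPKM against 24.1 ± 1.83 (limma adjusted p = 3.9e-08) and Il12b at 105 ± 3.67 against 4.27 ± 0.738. Ccl7 and Slc40a1 did not pass, at 46.8 ± 4.48 against 48.4 ± 9.06 and at 19.9 ± 3.71 against 18.1 ± 1.46. Tagap did not pass (limma adjusted p = 0.23) except without R837 replicate 2 (0.024) or with quantile normalization (0.037). Isg15 was higher by 1.13 on the log2 scale, Il12a by 0.96 and Hmox1 by 2.20.

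Of the lists, 14 were called and 9 held with an estimated correlation (limma camera). Higher were 27 of 30 cytokine and chemokine genes, all 22 NF-κB targets, 15 of 20 maturation genes, 21 of 35 interferon-stimulated genes, 15 of 22 NRF2 targets, 8 of 14 heat shock genes and 7 of 16 interleukin 4 response genes. Adjusted over the list alone the called genes, higher or lower, numbered 27, 22, 15, 25, 15, 11 and 8. The NRF2 and heat shock lists had not been called for R837 against control (limma camera adjusted p = 0.97 and 0.41). Lower were 18 of 27 lysosomal genes and 27 of 30 cell cycle genes, with 20 and 28 called when adjusted over the list alone. Heat shock rises numbered 5 without control replicate 2 or 3 or R837 with spermidine replicate 3. The brakes, LXR, MHC class I, Toll-like receptor 7 and oxidative phosphorylation lists had limma camera adjusted p-values of 7.7e-08, 0.014, 0.037, 0.042 and 0.012, and 0.063, 0.068, 0.39, 0.11 and 0.42 with an estimated correlation. The MHC class I call was lost without R837 with spermidine replicate 1 or 3 or control replicate 3 (0.056, 0.051 and 0.050), with quantile normalization (0.23) and with the filter on a mean FPKM of at least 5 (0.096), which also ended the cell cycle call (0.089). The Toll-like receptor 7 call was lost without R837 replicate 2, R837 with spermidine replicate 2 or control replicate 3 (0.066, 0.082 and 0.050), with quantile normalization (0.061), with no filter (0.061) and in a fit of both groups alone (0.073), and that of oxidative phosphorylation with median-of-ratios scaling (0.075). In all 1658 genes rose and 3850 fell (limma, adjusted p), and 62.9% were without overlap, where chance gives 10%. Median-of-ratios scaling gave 2395 and 2168, so the share of higher calls went from 30.1% to 52.5%, with quantile normalization at 43.8%.

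The effects of R837 and of added spermidine were opposed across genes. Over the 5081 genes called for R837 the correlation of both log2 changes was -0.56, and -0.18 (-0.26 to -0.13) in simulations that kept the R837 effect and had no spermidine effect. The covariance was -0.19 against -0.03. In all these simulations the noise was independent between genes, with 1 spread per gene pooled over the groups. The R837 libraries, which enter both changes, correlated less with one another than those of the other groups. The simulated correlations and covariances may therefore be too weak and their ranges too narrow. Over all tested genes the correlation was -0.44, within the range of -0.58 to -0.40 that simulations without any effect gave. Simulations that kept the R837 effect gave -0.15 (-0.20 to -0.10). The covariance over all tested genes was -0.10 against -0.02 in simulations without any effect, a difference of -0.08. Of the genes raised by R837, 535 fell with spermidine, where independent lists would share 128, and 64 rose (89.8 for independent lists). Of those lowered by R837, 358 rose with spermidine (195) and 110 fell (278). The R837 libraries enter both comparisons and 3 cannot be split into parts of at least 2. The simulations without a spermidine effect share those libraries. They gave at most 1 gene raised and then lower, and at most 1 lowered and then higher. With no effect almost no gene passes the adjustment, so these counts were fixed near 0 in advance. They cannot show how far the shared libraries skew the split of the real calls, and the independent lists ignore that sharing. Of the 588 genes raised by 2-fold or more, 313 fell with spermidine and 17 rose. Of the 372 lowered by as much, 91 rose and 5 fell. The log2 changes were also placed on a scale from 0 (control) to 1 (R837). On it the median position of the spermidine group was 0.72 for the raised genes and 0.83 for the lowered ones. The simulations gave 0.99 and 0.98. In FPKM itself a raised gene between both groups lies nearer to the control than on this log2 scale.

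Markers of other cell types were listed although the cells had been sorted. R837 replicate 3 held 815 FPKM of the haemoglobin gene Hbb-bs and 487 of Hba-a1, and R837 replicate 2 held 98.0 and 72.4, while in the other libraries Hbb-bs was at most 0.092 and Hba-a1 at most 4.95, in control replicate 1. Elane, a neutrophil granule gene, stood at 30.8 FPKM in R837 replicate 3 and at most 0.536 elsewhere, and the immunoglobulin gene Igkc at 46.4 in R837 replicate 3, 3.6 in R837 replicate 2 and 0 elsewhere. Of the 39 markers of 6 blood and marrow cell types that reached 1 FPKM in some library, 26 were highest in R837 replicate 3. These were 7 of 8 erythroid, 13 of 14 neutrophil, 3 of 3 B cell, 3 of 5 eosinophil, 0 of 3 T and NK cell and 0 of 6 basophil and mast cell genes. The dendritic cell integrin gene Itgax lay between 88.4 and 108 FPKM and the myeloid receptor gene Csf1r between 265 and 291 in the 9 libraries. Not every marker was as even. In R837 replicate 2 Itgam stood at 37.1 FPKM (104 to 173 elsewhere) and Adgre1 at 71.6 (116 to 173 elsewhere). Of the listed markers, 7 of 14 conventional dendritic cell and 16 of 19 macrophage genes reached 1 FPKM in some library. These levels do not show that the cell composition was equal. The macrophage, monocyte and conventional dendritic cell lists were not called in any comparison (limma camera), with adjusted p-values of 0.23, 0.12 and 0.12 for R837 against control. The neutrophil list was at 0.053, with 3 of 9 higher and 1 lower, and passed as higher without R837 replicate 1 (0.0086) and with no filter (0.014). Macrophage genes passed, as lower, with quantile normalization (0.034), and monocyte genes passed, as higher, for R837 with spermidine against control without R837 with spermidine replicate 2 (0.044). The erythroid list had 3 members past the filter, too few for the test. With the filter on a mean FPKM of at least 5 it was called up for R837 and down for added spermidine (limma camera adjusted p = 0.026 and 0.027), and likewise with no filter (0.0031 and 0.0015).

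Among the RNA quality lists, 0 of 28 ribosomal protein genes rose and 4 fell with R837 (limma camera adjusted p = 0.59), and 0 changed when spermidine was added (0.87). Without R837 replicate 2 the list passed as lower for R837 (0.041, with 13 lower) and as higher for added spermidine (0.044), and with quantile normalization 10 fell with R837 (0.0035). The falls with R837 numbered 1 without R837 replicate 1 or control replicate 1 and 2 without control replicate 2. Of 8 measured replication histone genes 3 fell with R837 and 1 with added spermidine, Hist1h1c from 26.3 ± 4.11 to 15.4 ± 2.21 FPKM, and the list was not called (0.72 and 0.16), but passed as lower for added spermidine with no filter (0.0031). Of the 15 listed histone genes 11 were highest in R837 replicate 3, as were many blood and marrow markers, with Hist1h2ak at 32.9 FPKM there and at most 1.10 elsewhere. The proliferation marker Mki67 stood at 28.9, 13.8 and 31.9 FPKM in R837 replicates 1, 2 and 3. The 13 protein-coding genes of the mitochondrial chromosome were listed at 0 in all libraries.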

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

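The correction for GC content was chosen after the data were seen, alone and with the replicate block. The other alternatives were fixed beforehand. Each alternative changed 1 choice, except the GC correction with the block, which changed 2.

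Among the counts of genes past the threshold, those of R837 against control ranged from 1379 to 1775 higher and from 2634 to 3805 lower when 1 library was left out. For R837 with spermidine against R837 they ranged from 290 to 739 and from 459 to 933, and for R837 with spermidine against control from 1342 to 2014 and from 3062 to 4498. A fit of the compared groups alone gave 301 higher and 456 lower for added spermidine, and 1471 and 2987 for R837 against control. For R837 with spermidine against control it gave more, 2009 and 4466. Each of these fits had fewer libraries behind the spread. The counts fell in the fits that hold the R837 libraries and rose in the fit without them. Libraries of the R837 group correlated less with one another (0.967 to 0.981) than those of the other groups. The fit of all 9 libraries gives the 3 groups 1 spread per gene, which may be too small for comparisons with R837. A required fold of 2 left 588 and 372 genes for R837 against control, 63 and 53 for added spermidine, and 470 and 321 for R837 with spermidine against control. A filter on a mean FPKM of at least 5 tested 6322 genes and gave 1842 lower for R837 and 2021 lower for R837 with spermidine against control. Median-of-ratios size factors gave 1941 and 2168 lower, by their construction, since they moved the median of all genes upward. Without the GC trend the counts were 1721 and 3974 for R837 against control, 842 and 1014 for added spermidine, and 1769 and 4137 for R837 with spermidine against control.

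The lists past the threshold numbered 14, 11 and 14 in the 3 comparisons, 5, 4 and 9 with an estimated correlation, and 23, 19 and 21 with fry, which asks another question. With 1 library left out they ranged from 12 to 15, from 9 to 12 and from 12 to 14. The correlation between the R837 and the added-spermidine changes was -0.56, lay between -0.59 and -0.55 with 1 library left out, and was -0.44 over all tested genes, which include genes R837 did not move.

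Of the 233 genes the rule named, 177 were called for R837 against control. Some alternative other than the required fold ended the call of 35, and the omission of a library that of 24. For added spermidine 126 were called, with 55 and 51 lost in the same ways. Many of those calls thus needed all libraries, and an omission also leaves fewer libraries behind the spread. Of the 56 and 107 uncalled genes, 31 and 29 gained a call under some alternative, and 24 and 31 changed sign. Of the called genes Ctss alone changed sign, to 0.16 with quantile normalization for R837 against control.

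Uncalled genes given in the text changed sign as follows, and the cause was not tested. With median-of-ratios size factors Smox was at 0.11 for R837 against control and Ccl7 at 0.16 for R837 with spermidine against control. Hmox1 was at -0.10 with quantile normalization for R837 against control. With weights per library H2-Ab1 was at -0.049 for R837 against control, Cd80 and Ifit1 at -0.25 and -0.17 for added spermidine, and Ccl7 at 0.0039. With the GC trend removed, with or without the replicate block, Ifit1 and Tlr7 were at -0.044 and -0.00021 for added spermidine. With 1 library left out H2-Ab1 ranged from -0.073 to 0.071 for R837 against control, and Ccl7 from -0.12 to 0.11 for R837 with spermidine against control. For added spermidine Cd80 ranged from -0.33 to 0.37, Ifit1 from -0.18 to 0.28 and Irf7 from -0.0019 to 0.12.

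The samples share replicate numbers. Deviations of libraries with the same number correlated across genes at -0.03, 0.13 and -0.03 between R837 and control, at -0.09, 0.16 and 0.02 between R837 with spermidine and control, and at 0.04, -0.06 and 0.05 between both R837 groups. Control replicate 2 correlated best with its own number in both other groups, but most pairs stayed below 0.1, so the numbers were not taken to pair the samples. With the replicate number as a block the counts were 1541 and 3272 for R837 against control, 470 and 661 for added spermidine, and 1607 and 3638 for R837 with spermidine against control. The lists numbered 15, 11 and 13, and the correlation between both changes was -0.57. None of these totals moved by more than 1.5 times with the block. Within lists, for added spermidine, unfolded protein response rises went from 7 to 3, cell cycle falls from 5 to 3 and MHC class I falls from 4 to 2, and other small counts moved as well. The block ended the limma camera call of the Toll-like receptor 7 list for R837 with spermidine against control (adjusted p = 0.052) and gave a call to the neutrophil list for R837 against control (0.035). Together with the GC correction it ended the MHC class II call for added spermidine (0.057), and the brakes stayed uncalled as with the correction alone (0.085). At the depths of these libraries, values near 1 FPKM rest on few units, so absence of a call there says little.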

Other observations

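The tests of an equal proportional loss, of oxidation products and of blood and marrow markers were chosen after the result was seen, as was the GC correction; the counts over other splits were fixed beforehand. The test of an equal loss took the place of an exact permutation test, whose result 3 against 3 libraries had fixed above 0.05.

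With added spermidine 23 of 30 cytokine and chemokine genes fell, and 1 of 35 interferon-stimulated genes. Removal of the GC trend left 24 of 30 cytokine and chemokine members lower, and omission of R837 replicate 3 left 22 of 30. The GC trend, and other cells in that library, are thus not the whole cause. R837 replicate 2, with Hbb-bs at 98.0 FPKM, stayed in the fit without replicate 3. Other cells in both libraries were therefore not tested. The share of the rise with R837 that was kept was taken on the mean log2(FPKM + 1) of the members. The 3 spermidine libraries kept 0.70, 0.63 and 0.66 over 28 cytokine members, and 0.98, 0.99 and 1.00 over 18 interferon-stimulated members. In FPKM itself a share between 0 and 1 of a rise is smaller than on this log2 scale. The difference between both lists, set against that in the R837 libraries, was 0.33 ± 0.056 (SE, 95% interval 0.14 to 0.52). On the log2 scale an equal proportional loss of the whole rise over the controls is thus argued against. Spermidine may act on cytokine transcription more than on the interferon response, but the interferon-stimulated genes may also owe their level to the priming, in which case an equal loss of the effect of R837 itself stays open.

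NRF2 targets rose with added spermidine. Removal of the GC trend left 18 of 22 members higher and omission of R837 replicate 2 left 18 of 22, so neither is the whole cause of the rise. Per the labels the medium held fetal bovine serum, whose amine oxidases can turn spermidine into reactive aldehydes and hydrogen peroxide. Such products may be the source of the stress response, and 7 of 14 heat shock members also rose. That explanation and a direct effect of spermidine cannot be told apart, because no group had an amine oxidase inhibitor, serum-free medium or spermidine alone.

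Markers of other blood and marrow cells were high in R837 replicate 3, which was the highest library for 26 of 39. Cells or RNA of such types in that library are a candidate explanation, with Hbb-bs at 815 FPKM and Elane at 30.8, although the protocol had a flow sort. Induction by R837 is argued against, since all 3 R837 libraries lay above all controls for 4 of the 26. For those 4, all on the neutrophil list, some induction stays open. Of the 74 listed markers 20 had a control mean of 1 FPKM or more, and whether the cultured cells express these themselves was not tested. The count of 26 of 39 that goes with other cells is the observed pattern itself. No biological explanation apart from induction and other cells was tested.

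Each comparison of 3 against 3 libraries allows 10 splits, so the share of splits with a result as large is never under 0.1, too high for chance to be tested at 0.05. In each of the 6 tests 1 split, the real one, gave the result. The real splits called 5081 genes for R837 against control, 1601 for added spermidine and 5508 for R837 with spermidine against control, and the highest of the other splits called 1, 1 and 2. For lists the real splits gave 14, 11 and 14, and the highest of the others gave 12, 10 and 11. Every other split mixes libraries of both groups, so it keeps part of the real effect and widens the spread. Neither its gene count nor its list count therefore shows what libraries without an effect would give. The weight of the number of camera calls cannot be judged from these splits.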
